A study of Mus musculus with 20 samples.

How the data were processed

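The values analysed were RPKM (reads per kilobase of gene and per 1000000 reads) for 39179 Ensembl genes in 20 single cells, in a single table deposited by the authors. Its title line names 39173 IDs. Per the submitters' processing notes, TopHat2 2.0.12, HTSeq 0.6.1 and build GRCm38 were used; their settings, and whether reads aligned to several places were counted, are not given in the sources used here. Each library is 1 cell of 1 mouse, so the animal is the only biological unit and cells are not replicates of a treatment. In the table, 1 blank value was set to 0. Gene symbols were taken by Ensembl ID from GENCODE M21, which matched 37607 IDs, and otherwise from the table; coordinates are from the same release, on GRCm38 and counted from 1.

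The depth was recovered from the values. An RPKM value is a whole number of reads divided by the gene's length and the library's total, so ratios of low values between libraries give the ratio of their totals. The scale was set by 1421 genes for which the annotated exonic length gave the same total. With these totals, a whole-base length gave whole reads, within 0.001 read, in every cell for 13170 of 13170 genes with reads in at least 2 cells. No count test was run, because there are no groups. The gene length recovered from the deposited values was the mean length of a gene's annotated transcripts, within 1 base, for 45.2% of 10407 genes with several transcripts, and the exonic union for 0.471%. These 2 percentages are not a like comparison. A multiple of the smallest fitting length was taken where it came within 1 base of the mean transcript length, and no such step was made for the exonic union. The median recovered length was 42.4% of the exonic union, so genes with many short transcripts have raised RPKM values. Lengths kept as a fraction of the true ones may also lower that median. Of the 25 genes with the highest medians, 22 were the same with the length of the longest transcript, but the leading genes changed order. Values were not rescaled; they summed to 542042 to 611232 per cell. The 190 pairs of cells had Pearson correlations of log2(RPKM + 1) from 0.43 to 0.62, and no pair shared a nonzero value, compared exactly as deposited, with no rounding or tolerance.

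A gene was called found in a cell at 1 RPKM or more. Gene lists were fixed before the data were examined: 8 lists of cell type markers (podocyte, endothelial, mesangial and mural, parietal epithelial, proximal tubule, distal tubule and collecting duct, immune, red cell) and 25 gene groups (slit diaphragm, actin, integrin adhesion, basement membrane, transcription factors, inherited nephrotic disease, immediate early, heat shock, proliferation, inhibitors of cyclin-dependent kinases, mitochondrial, nuclear respiratory chain, ribosomal, glycolysis, fatty acid oxidation, lysosome and autophagy, endoplasmic reticulum chaperones and stress, secreted signals, complement, antigen presentation, hormone receptors, genes known from neurons, filaments and microtubules, reference genes and sex-linked genes). Of their genes, 500 were measured and 2 red cell genes could not be matched. The genes named were those of these lists, the 25 with the highest median, the 15 with the lowest and the 15 with the highest variation at their level (the latter found in at least 3 cells), the 15 highest of the genes found in 5 to 15 cells with a median of at least 50 RPKM where found, and the 10 found in every cell with the highest minimum. Predicted genes and pseudogenes were counted but not described. Values of 2 podocyte genes enter the counts and are not reported here.

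Cell-to-cell variation was the residual of log2 squared coefficient of variation from a loess trend (span 0.3) on log2 mean, over 5470 genes with a mean of at least 10 RPKM. Covariation was the median pairwise Spearman correlation over the 20 cells. A list was called outside the range in the lowest or highest 2.5% of random lists. Lists with at least 5 such genes were set against 10000 random lists drawn within 20 bins of mean expression, and the percentile is a description of these libraries, not a test. On simulated data for those 5470 genes, 14 of 20 planted covarying lists and 20 of 20 planted variable lists of 20 genes lay in the highest 2.5% of random lists, and 4.75% and 6.25% of 400 random lists lay outside the range. Read recovery, tested on 12000 simulated genes that all had their mean transcript length, returned all 20 totals and 100% of nonzero values. This does not cover genes of another length. For those the smallest length that gave whole reads was kept, so their reads and length could be a fraction of the true ones.

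Alternatives were detection above 0 and at 5 RPKM, rescaling each cell to a sum of 1000000, leaving out the cell with the fewest genes, a pseudocount of 0.1 in place of 1, the median over a list, minimum means of 1 and 50 RPKM, the SD of log2(RPKM + 1), Pearson correlation, and removal of the number of genes per cell. Added after seeing the data were detection at 10 reads, the longest-transcript length, and leaving out 6 cells with at least 4 markers of 1 other type. Near-identical copies were sought with BLAST 2.17.0 against GENCODE transcripts at 97% identity. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.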

Results

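The series holds RNA sequencing libraries of 20 single podocytes, the epithelial cells that wrap the capillaries of the kidney filter, from 1 wild-type male C57BL/6 mouse aged 8 weeks. Glomeruli were collected with magnetic beads and digested with enzymes, and the cells were captured and their cDNA made on a Fluidigm C1 instrument, which isolates cells in separate wells. All 20 cells form 1 group and come from 1 animal. No comparison between groups was possible, so no p-value is given, and every SD describes the spread between cells of this mouse. Cells are named by their replicate number. The reads assigned to genes ranged from 4205562 in cell 15 to 10448491 in cell 17, with a median of 6753753. In a gene of 2000 bases, 1 read stood for 0.0479 to 0.119 RPKM (reads per kilobase of gene and per 1000000 reads). A gene with no read in a library could therefore lie at up to 0.144 to 0.357 RPKM there, the value of 3 reads. These limits cover counting error only, because amplified reads are not independent molecules.

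Few genes were found in all 20 cells, and most genes found in at least 1 cell were found in only a part of the cells. Of 39179 genes in the table, 11749 reached 1 RPKM in at least 1 cell, and 260 did so in every cell. Another 2602 genes were found in exactly 1 cell, and 61.5% of the genes found were found in at most 5 cells. A cell held a median of 3306 genes (SD 664, n = 20 cells), from 2371 in cell 12 to 4977 in cell 10. The threshold set these counts: above 0 RPKM, 6105 genes per cell and 874 genes in every cell were counted.

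**Figure D1:**
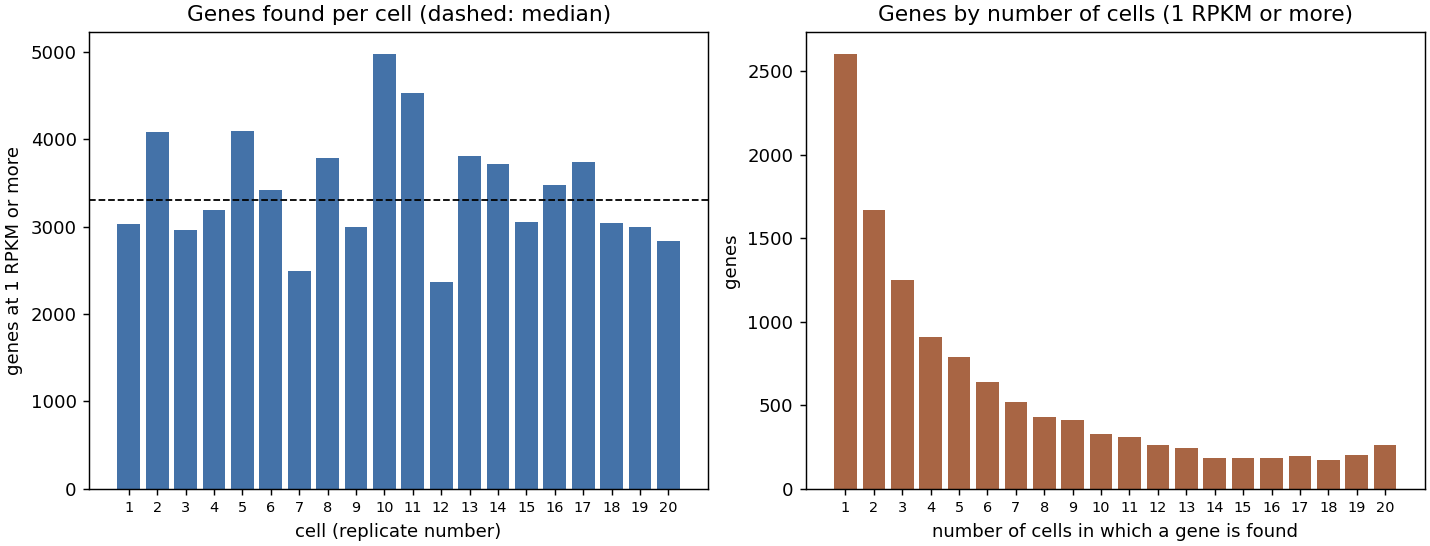
Left, bars give the number of genes at 1 RPKM or more in each of the 20 cells, with the median of 3306 as a dashed line; right, bars give the number of genes by the number of cells in which they were found. Most of the genes found in at least 1 cell were found in few cells, and 260 were found in all 20.

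Malat1, a nuclear long noncoding RNA, had the highest median level, at 25889 RPKM (mean 26582 ± 7391, SD, n = 20 cells), and took 2.58% to 7.65% of the reads of a cell. Sdc4, a heparan sulfate proteoglycan of the cell surface, followed with a median of 15262 RPKM, and Actb, cytoplasmic actin, with 13918 RPKM. This order depends on the gene length behind the values. That length was 1867 bases for Malat1, 1628 for Sdc4 and 956 for Actb, against longest transcripts of 6983, 2458 and 1920. For mt-Atp6 it was 681 bases by both measures. With the longest transcript as length, the median of mt-Atp6 would lie above those of Malat1, Sdc4 and Actb. Of the 25 genes with the highest medians, 8 were mitochondrial, led by mt-Atp6 at 10239 RPKM and mt-Co3 at 8524 RPKM. The others included Tmsb4x, an actin monomer binding peptide, at 5147 RPKM, the septins Sept2 at 5917 RPKM and Sept11 at 2199 RPKM, and the calcium sensor Calm2 at 3897 RPKM. Canx, a chaperone of the endoplasmic reticulum, had a median of 3291 RPKM and the complement inhibitor Cd59a one of 2273 RPKM. Malat1, Sdc4, Actb and Tmsb4x did not fall below 13822, 7687, 6597 and 2919 RPKM in any cell. The sequences of mt-Atp6, mt-Co1, mt-Co2, mt-Co3 and mt-Nd4 have a near-identical copy elsewhere, so their levels are uncertain.

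Podocyte markers were found throughout the 20 cells. Of the 20 markers fixed before the data were examined, a cell held a median of 18 at 1 RPKM or more, from 17 to 20. Found in every cell were 15, among them Nphs1, which encodes nephrin of the slit diaphragm, and Wt1, a transcription factor needed for podocyte development. Nphs1 (chromosome 7, 30458315 to 30487223, build GRCm38) had a mean of 478 ± 500 RPKM (SD, n = 20 cells) and a median of 2974 reads, and ranged from 48.9 RPKM in cell 5 to 1639 RPKM in cell 17. Wt1 (chromosome 2, 105126529 to 105173616) had a mean of 1037 ± 418 RPKM, Podxl, a sialomucin of the foot process surface, 1050 ± 646 RPKM, Synpo, an actin-associated protein, 395 ± 273 RPKM, and Cdkn1c, an inhibitor of the cell cycle, 1783 ± 972 RPKM. Tcf21 was found in 19 cells, Rhpn1 in 18 and Dach1 in 17. Lmx1b, a transcription factor, was found in 8 cells, with a median of 0.350 RPKM, and Pla2r1 in 3. Pla2r1 had 1171, 792 and 8579 reads in cells 10, 11 and 14, and at most 19 in any other. Each of these 3 cells also held mesangial markers, as given below. In all 20 cells the mean log2(RPKM + 1) of the podocyte markers was above that of each of the 7 other marker lists. How the 20 cells were chosen is not given in the sources used here, so these markers are not independent evidence of identity.

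Mesangial and mural markers were high in 5 cells. Cells 5, 6, 10, 11 and 14 held 6 to 10 of the 14 markers, while each of the other 15 cells held at most 1. Gata3, a transcription factor of mesangial cells, lay between 693 and 1550 RPKM in those 5 cells and reached at most 1.62 RPKM elsewhere. Sfrp2, a secreted Wnt antagonist, Serpine2, a protease inhibitor, Itga8, an integrin subunit, Ptn, a growth factor, and Myl9, a myosin light chain, were found in the same 5 cells and no other. In cells 5, 6, 10, 11 and 14, in that order, Sfrp2 stood at 924, 564, 966, 1357 and 289 RPKM and Itga8 at 831, 245, 587, 919 and 94.8 RPKM; Serpine2 ranged from 128 to 1365 RPKM. Rgs5 was found in cells 5, 6 and 10, at 126 to 397 RPKM. The smooth muscle genes Acta2 and Tagln and the renin gene Ren1 were found in no cell. Pdgfrb, a receptor of mural cells, was also found in cells 8 and 13, at 6.34 and 84.4 RPKM. These 5 cells also held 17 to 20 podocyte markers and 4 to 8 of the 16 endothelial markers. The podocyte count includes Pla2r1 in cells 10, 11 and 14, the only cells in which it was found.

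Endothelial markers were most numerous in cell 8, with 13 of 16 found, followed by cell 10 with 8. Pecam1, an adhesion molecule, stood at 81.0 RPKM there, Kdr and Flt1, receptors for vascular endothelial growth factor, at 148 and 93.2 RPKM, Emcn at 1337 RPKM and Esam at 660 RPKM. Pecam1, Kdr, Flt1, Cdh5 and Tie1 were found at 1 RPKM in no other cell. Emcn was also at 315 RPKM in cell 5, 151 RPKM in cell 10 and 7.65 RPKM in cell 11, and Egfl7 and Erg were found in no cell. Plat, tissue plasminogen activator, was found in every cell, with a median of 682 RPKM, and Cldn5 in 8 cells. Plat, Tek, Ehd3 and Cldn5 were not highest in cell 8. Plat had 52431 reads in cell 17 and 36822 in cell 8. Tek had 3727 reads in cell 11 and 53 in cell 8, and Ehd3 5281 in cell 5 and 3384 in cell 8. Cldn5 had 3739 reads in cell 12 and 1 in cell 8. Of the 8 parietal epithelial markers, Krt7 was found in 12 cells, with a median of 6.82 RPKM, and 4 in no cell; Pax8 stood at 382 RPKM in cell 2 and Aldh1a2 at 315 RPKM in cell 13. Tubule, immune and red cell markers were nearly all below 1 RPKM. Of 14 proximal tubule markers, 13 were found in no cell, as were 9 of 10 of the distal tubule and collecting duct, 11 of 12 immune markers and all 5 measured red cell genes. The exceptions were Cyp4b1, at 315 RPKM in cell 8, Calb1, at up to 1.62 RPKM, and Fcer1g, at 495 RPKM in cell 5. Over all other types a cell held a median of 3 markers, from 1 to 19.

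**Figure D2:**
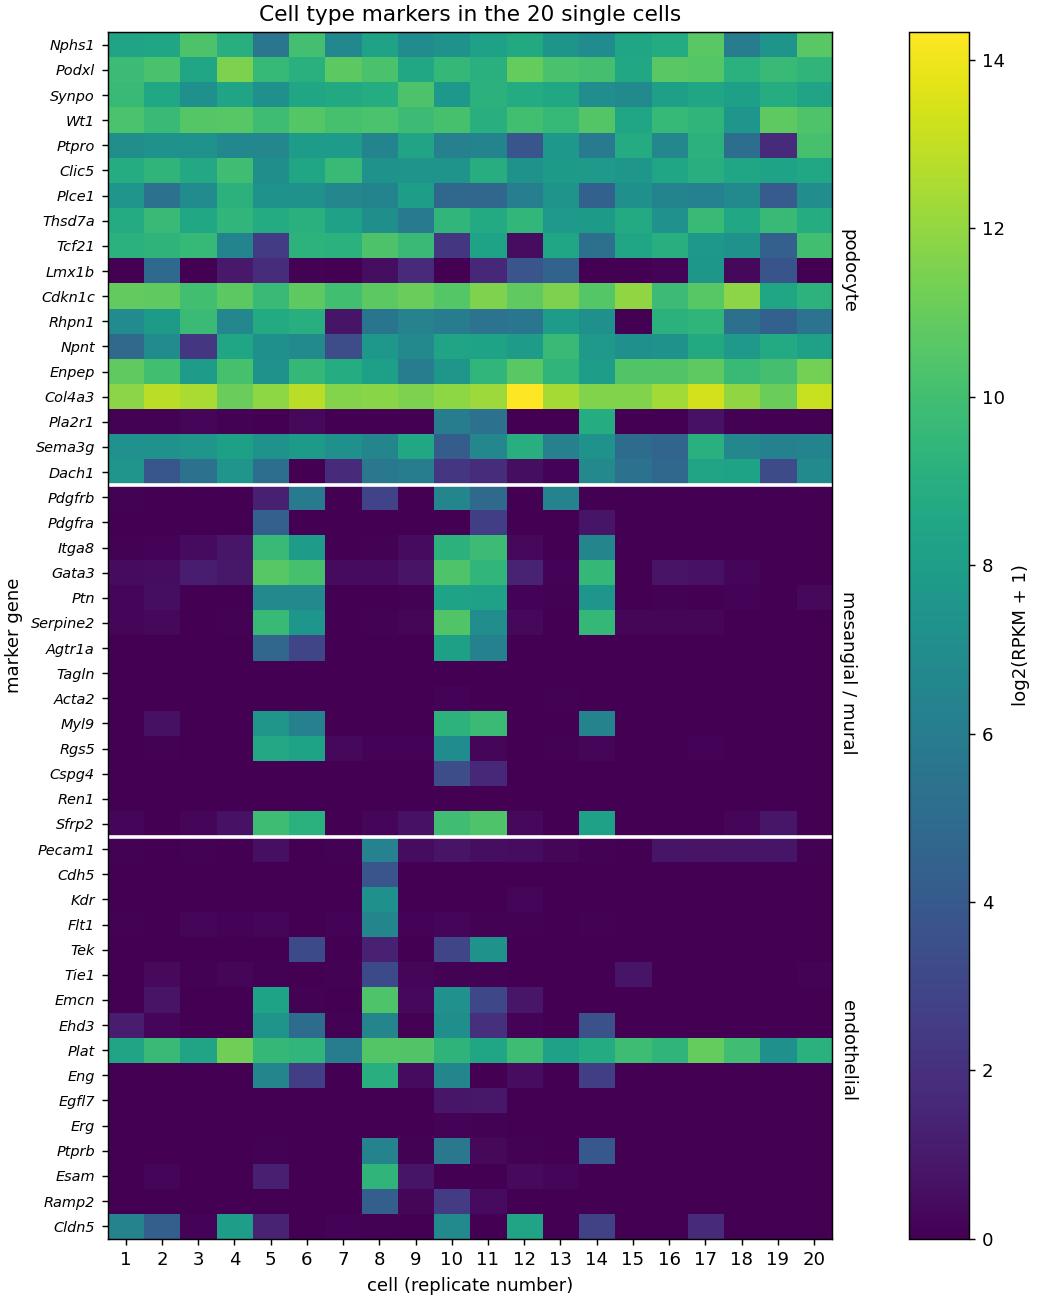
Each row is a marker of the podocyte, mesangial or mural, or endothelial lists, each column a cell by replicate number, and the colour gives log2(RPKM + 1). Most podocyte markers fill all 20 columns, most mesangial markers appear in cells 5, 6, 10, 11 and 14, and most endothelial markers appear in cell 8.

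Of 23 slit diaphragm genes, 6 were found in every cell, among them Magi2, a scaffold, with a median of 67.5 RPKM, and Nck2, an adaptor to actin, with 286 RPKM. Cd2ap was found in 18 cells, Crb2 in 13 and Kirrel, a partner of nephrin, in 12. Kirrel2, Kirrel3, Pard6a and the calcium channel gene Trpc6 had no read in any cell. Collagen IV genes differed widely. Col4a3 (chromosome 1, 82586921 to 82722059) had a median of 3895 RPKM and 92366 reads per cell. Its neighbour Col4a4 (chromosome 1, 82448423 to 82586849), whose product assembles with it in the adult basement membrane, had 49.7 RPKM and 1126 reads, and Col4a5 had 6.67 RPKM and was found in 14 cells. Col4a1 and Col4a2 were found in 5 and 4 cells. Of the 16 basement membrane genes, 3 were found in every cell, namely Col4a3, Npnt and Sparc, the last with a median of 1816 RPKM. Lama5 was found in 7 cells and Lamb2 in 8.

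Among 18 transcription factor genes, 2 were found in every cell, among them Wt1, and Hey1 in none. Another 10 were found in 5 to 15 cells, among them Foxc2 in 15, Foxc1 in 12 and Yap1 in 13. Of 56 genes of inherited nephrotic disease, 12 were found in every cell, and 21 in fewer than 5, of which 8 in no cell; Plce1 had a median of 103 RPKM, Arhgap24 377 RPKM and Myh9 399 RPKM. Of 32 actin regulators, 7 were found in every cell, led by Actr2 of the Arp2/3 complex at a median of 1432 RPKM. Anln, a scaffold of the contractile ring, reached 1 RPKM in no cell. Integrin adhesion genes had 4 of 17 in every cell, including Itgb1 at 354 RPKM and Parva at 133 RPKM, while Ilk was found in 1 cell. Vim, an intermediate filament gene, was found in 19 cells at a median of 470 RPKM, and 0 of the 15 filament and microtubule genes were found in all 20; Krt8 and Krt18 had no read. Among 17 genes known from neurons, Rab3b at 850 RPKM and Dpysl2 at 1406 RPKM were found in every cell, and 6 in none, among them Syn1.

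Immediate early genes were mostly found in few cells, with 15 of 21 in fewer than 5. Of the 21, 8 reached 1 RPKM in no cell, including Fos, Fosb, Junb, Egr1, Atf3 and Myc, and none did so in every cell. Klf6 and Jund were found in 15 cells, at medians of 25.9 and 4.27 RPKM, and Jun in 11 at 3.91 RPKM. None of the 12 heat shock genes was found in every cell; Hsp90ab1 had a median of 1627 RPKM and Hsp90aa1, much of whose sequence has near-identical copies, 0.218 RPKM. Proliferation genes were mostly not found, with 13 of 19 in no cell, including Mki67, Cdk1 and Mcm2; Top2a was found in 15 cells at a median of 2.71 RPKM. Of the 7 inhibitors of cyclin-dependent kinases, Cdkn1c was in every cell, Cdkn1b in 19 and Cdkn1a in none. Of 12 chaperone and stress genes of the endoplasmic reticulum, 4 were found in every cell, among them Canx and Hsp90b1, the latter at a median of 738 RPKM. The stress-induced transcription factor genes Atf4 and Ddit3 were found in 7 and 6 cells.

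Of the 13 protein genes of the mitochondrial genome, 12 were found in every cell; the exception, mt-Nd4l, was found in none. It has a near-identical copy, as do 6 of the 12, so the copy does not set it apart. Ribosomal protein genes were all found, 10 of 31 in every cell, though 11 of them have near-identical copies. The 28 nuclear genes of the respiratory chain were likewise all found, 5 of them in every cell. Glycolysis genes were low: none of 13 was found in every cell, and the median of their medians was 1.01 RPKM, against 86.9 RPKM for the nuclear respiratory chain. Aldoa was the exception, at 353 RPKM in 19 cells. Gapdh was found in 14 cells at a median of 9.62 RPKM, and Ldha in 7. Fatty acid oxidation genes had 10 of 13 in 5 to 15 cells, and the median of their medians was 1.20 RPKM. Etfb was found in 16 cells, at a median of 154 RPKM. Of 14 lysosome and autophagy genes, Ctsl, a lysosomal protease, was the 1 gene in every cell, at 563 RPKM. Of 15 common reference genes, 3 were found in every cell, namely Actb, Tmsb4x and Eef1a1, the last with 2 near-identical copies.

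Vegfa, the growth factor for the adjacent endothelium, had a mean of 310 ± 203 RPKM (SD, n = 20 cells) and was in every cell, as were Sema3g and Igfbp7. Of the 18 secreted signals, 7 reached 1 RPKM in no cell, including Angpt1 and Tgfb1. Of 8 complement genes, Cd59a was in every cell and Cd55 in 18. In antigen presentation, H2-D1 and B2m were found in 19 cells and 5 of 10 genes in none. Of 17 hormone receptor genes, none was in every cell; Npr3 was found in 17 cells at a median of 98.3 RPKM, Npr1 in 13 and Nr3c1, the glucocorticoid receptor gene, in 11. For the stated male sex, Ddx3y was found in 14 cells, Eif2s3y in 11, Uty in 9 and Kdm5d in 1. Xist, the X-inactivation RNA, reached at most 0.337 RPKM.

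Many genes were high in some of the 20 libraries and not found in others. Loss of transcripts at capture or amplification could also leave a gene not found, and was not told apart from absence of expression. There were 1354 genes found in 5 to 15 cells with a median of at least 50 RPKM where found. Myl7, an atrial myosin light chain, was found in 5 cells at a median of 1048 RPKM, and Ptp4a1, a phosphatase, in 15 at 931 RPKM. Zbtb38 was found in 15 cells at 756 RPKM and Synj2bp in 14 at 679 RPKM. Sfrp2, Serpine2, Gata3 and Itga8 of the mesangial list were also among the 15 highest. Above 0 RPKM, the count of such genes was 261. Relative to other genes of their level, the largest cell-to-cell variation among genes found in at least 3 cells was seen for Sec13, a coat protein of secretory vesicles, found in 8 cells with 2611 RPKM in cell 19, and included Sgk1, a kinase induced by corticosteroids, at 2105 RPKM in cell 5, 1372 RPKM in cell 10 and 323 RPKM in cell 11. These 3 cells are among the 5 with mesangial markers, of which cells 14 and 6 held 35.3 and 0.568 RPKM of Sgk1, and no other cell held more than 16.8 RPKM. Anxa1, an inhibitor of inflammation, was found in 19 cells and ranged from 0.451 to 8290 RPKM. The smallest variation was seen for Aox1, an oxidase of aldehydes, at 11.8 ± 6.49 RPKM (SD, n = 20 cells), followed by Hsd3b2 at 11.9 ± 7.77 RPKM; Rpl37 was also among the 15 lowest, at 81.9 ± 36.0 RPKM.

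Ribosomal, transcription factor, nephrotic disease, actin, basement membrane and secreted signal genes varied less from cell to cell than other genes of their level. As a description of these libraries, each list's median residual variation was set against 10000 random lists of the same size and expression. The ribosomal list lay at percentile 0, the transcription factor and nephrotic disease lists at 0.12, actin at 0.44, basement membrane at 0.805 and secreted signals at 1.1. The mesangial list was the 1 list above the range, at 99.4. These 7 of 23 lists lay in the lowest or highest 2.5% of random lists, where chance would place 1.15. The lists share genes, so the 7 calls are not separate results. The nephrotic disease list holds Actn4, Myh9 and Arhgap24 of the actin list. It also holds Col4a3 of the basement membrane list and Wt1 of the transcription factor list. With the SD of log2(RPKM + 1) in place of the coefficient of variation, the transcription factor, basement membrane, secreted signal and actin lists lay inside the range, at 34.4, 16.1, 5.75 and 3.06, whereas the podocyte and slit diaphragm lists lay below it, both at 0.01, the mitochondrial list below it, at 0, and fatty acid oxidation genes above it, at 99.4. The podocyte list, at 19.2 with the coefficient of variation, lay at 0.22 without cells 5, 6, 8, 10, 11 and 14 and at 1.24 among genes with a mean of at least 50 RPKM. Genes known from neurons, at 3.34, lay below the range in 4 of 6 alternatives, at 0.175 to 2.03. Without cells 5, 6, 8, 10, 11 and 14 the basement membrane list lay at 3.76, and among genes with a mean of at least 1 RPKM the secreted signal list lay at 4.2 and the mesangial list inside the range.

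Mesangial genes rose and fell together across cells, with a median pairwise Spearman correlation of 0.664 against 0.0174 for random lists (percentile 100). This value restates the pattern given above, in which most of these markers were found in the same cells. Endothelial (0.315, percentile 99.9), filament and microtubule (0.136, 98.3) and mitochondrial genes (0.103, 98.8) also lay above the range, as did ribosomal (0.0949, percentile 99.99), podocyte (0.0827, 99.5) and reference genes (0.0803, 97.7). These were 7 of 23 lists, none below the range. The endothelial value rests on 6 of the 16 genes, without Pecam1, Kdr and Flt1, whose means were too low. It may in part restate the markers given above for cell 8 and the cells with mesangial markers. Without cells 5, 6, 8, 10, 11 and 14, which held at least 4 markers of 1 other type, the count was 4 of 21 lists and the podocyte list lay at percentile 90.3. The mesangial and endothelial lists then held too few genes to be measured. Without cell 12, which held the fewest genes, the ribosomal and reference lists lay inside the range, at 77.2 and 95.8, and the reference list did so in all 7 alternatives. The podocyte list lay at 88.6 with Pearson correlation, and the filament and microtubule list at 86.5 among genes with a mean of at least 50 RPKM.

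**Figure D3:**
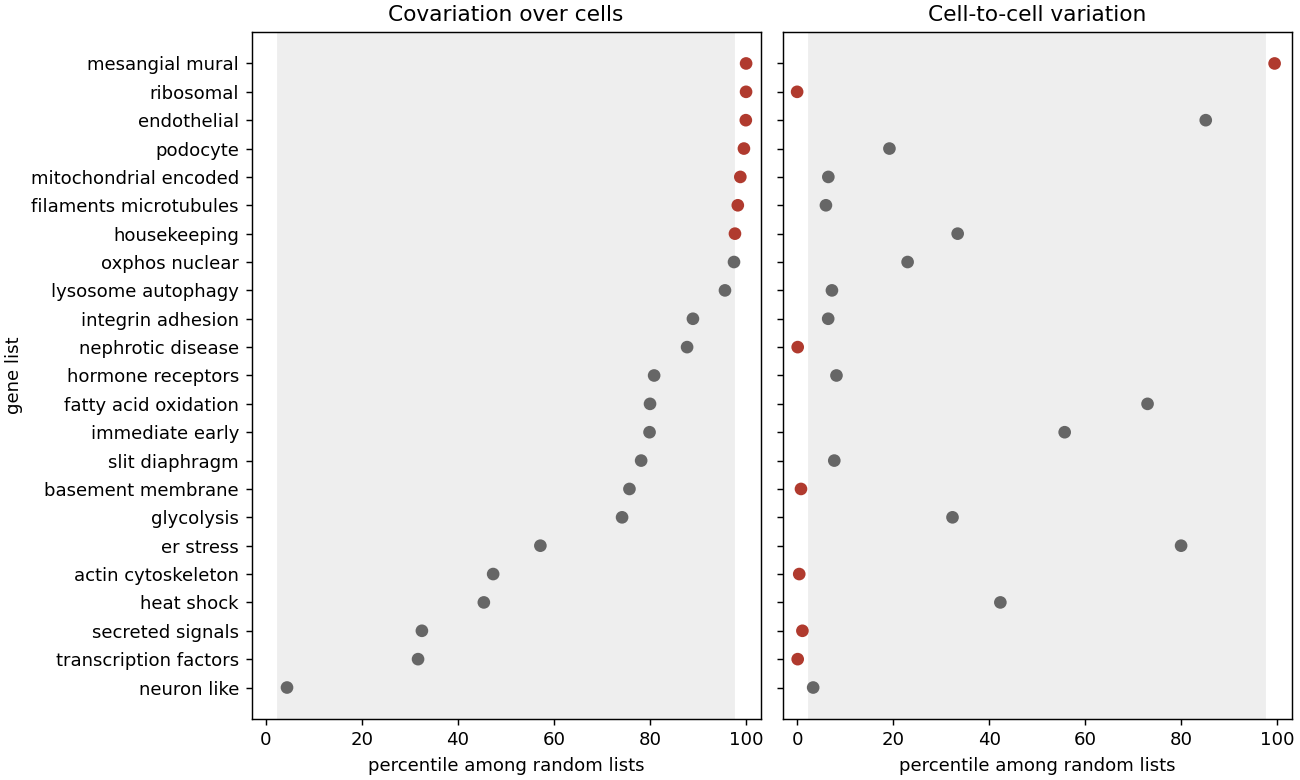
Points give each gene list's percentile among 10000 random lists, left for the median pairwise Spearman correlation over cells and right for cell-to-cell variation at a given level; the grey band leaves out the lowest and the highest 2.5%, and red points lie outside it. For covariation 7 lists lie above the band; for variation 6 lie below and 1 above.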

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

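Of 52 alternative values, 34 planned and 18 chosen after seeing the data, 44 stayed within the spread between cells or within 1.5 times the count. For gene lists only the number outside the range was compared, not which lists they were. The SD of log2(RPKM + 1) kept the number at 7, of which 3 were among the original 7. At a minimum mean of 50 RPKM, 5 lists covaried, of which 4 were among the original 7. Counting genes above 0 RPKM moved the median genes per cell to 6105, podocyte markers to 19, other-type markers to 13.5, genes in every cell to 874 and genes found in 5 to 15 cells at a high level to 261; this counts single reads as detection. At 5 RPKM, genes per cell were 2511 and genes in every cell 172. Without the 6 cells with at least 4 markers of 1 other type, covarying lists numbered 4, of which 3 were among the 7 found with all cells; the mesangial and endothelial lists then held too few genes to be measured. The podocyte markers had the highest mean in 20 of 20 cells under the other pseudocount and scale, and in 19 with the median in place of the mean. For variation, mesangial genes stayed outside the range in 4 of 5 alternatives. Among lists of low variation, ribosomal and nephrotic disease genes stayed outside the range in all 6 alternatives, and actin and transcription factor genes in 5, the exception being the SD of log2(RPKM + 1), with percentiles of 3.06 and 34.4. Basement membrane genes stayed outside in 3 of 5 and secreted signals in 2 of 5. Lists inside the range in the main analysis also left it: for variation, genes known from neurons, at percentile 3.34, lay below it in 4 of 6 alternatives, podocyte genes in 3 of 6, and slit diaphragm, integrin adhesion and mitochondrial genes in 1 of 6, and fatty acid oxidation genes lay above it in 1 of 6. For covariation, nuclear respiratory chain and lysosome and autophagy genes lay above it in 2 of 7 alternatives, and glycolysis and nephrotic disease genes in 1 of 7. Of the covarying lists, mitochondrial genes stayed outside in 7 of 7, mesangial in 6 of 6, endothelial in 5 of 5, filament and ribosomal genes in 6 of 7, podocyte genes in 4 of 7 and reference genes in 0 of 7. The cause of these moves was not tested. No paired analysis was possible because there is 1 group. Depth leaves a gene of 2000 bases below 0.357 RPKM unresolved in the shallowest library.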

Other observations

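All tests in this part were chosen after the results were seen, and no biological explanation was tested, because the design has 1 group. Beyond the fixed markers, the 5 cells with mesangial markers shared further genes. Of 791 genes found in exactly 5 cells, 18 were found in exactly cells 5, 6, 10, 11 and 14, and no other set of 5 cells shared more than 5. Besides Sfrp2, Serpine2, Itga8, Myl9 and Ptn they included Lmo7 at 145 to 622 RPKM, Bgn, the proteoglycan biglycan, at 15.5 to 859 RPKM, the matrix protease gene Adamts5 at 112 to 354 RPKM and Dkk2, a Wnt antagonist, at 15.7 to 243 RPKM. These 4 genes were named after their values were seen. The comparison with other sets of 5 cells is not a like one. The cells were picked by mesangial markers, 5 of which are among the 18 genes, and they ranked 1, 2, 3, 8 and 10 by genes found. Some of the 18 lay near the threshold in a cell, such as Mtap at 1.20 RPKM and Fhl2 at 1.29 RPKM.

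The mesangial markers in 5 cells were weighed against misassigned reads and a second cell; because the other 15 cells held at most 1 marker, free RNA alike in all wells does not describe the pattern, and free RNA in some wells stays open. Misassigned reads are argued against: over 11 markers, the second-highest cell held a median of 66.2% of the reads of the highest, and at least 20.9%, whereas misassignment would bring every gene of a source along, and in each of the 380 ordered pairs of cells the lowest 10% of genes with at least 1000 reads in the source stayed at or below 0.0767% of those reads in the recipient. With at least 5000 and 10000 reads in the source, which leave as few as 167 and 51 genes, that value was up to 2.49% and 30.7%. A second cell in the same well remains a candidate explanation. All 6 cells with at least 4 markers of 1 other type were among the 10 with the most genes. This rank cannot single it out, because cells picked for holding more markers may hold more genes under any explanation left open. A cell that itself expresses podocyte and mesangial genes would also hold more genes and stays open. Sfrp2 and Gata3 reached 1357 and 1550 RPKM, and Acta2 and Tagln of contractile mural cells were found in no cell. Of the 14 markers, 1, Agtr1a, is also in the hormone receptor list. The 5 cells also held 4 to 8 endothelial markers, against a median of 2 over all cells. A second cell with mesangial markers only would not describe that excess. A single cell expressing podocyte and mesangial genes only would not either. The source of these endothelial markers was not tested.

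Most glycolysis genes had low medians over the 20 cells. Of 6 genes that share under 10% of their longest transcript with other loci, 5 had medians below 10 RPKM (Hk1, Pfkl, Pfkm, Pfkp and Ldha), Aldoa being the exception, so shared reads do not account for those 5. The other 7 (Gapdh, Gpi1, Tpi1, Pgam1, Eno1, Pgk1 and Pkm) share 19.3% to 85.6% and also had medians below 10 RPKM, though each reached 10 RPKM in 2 to 10 cells, Gapdh in 10. Not every gene with much shared sequence was low: Rplp1 and Eef1a1, which share 99.4% and 83.4%, had medians of 111 and 917 RPKM. Whether these 2 genes also lost reads is not known, so they do not show that sharing left the glycolysis genes unchanged. If reads lay evenly along a gene and all those on shared sequence were lost, restoring them would put Pgam1, Gpi1, Tpi1, Pkm and Pgk1 at medians of 0 to 5.60 RPKM, still below 10, and Eno1 and Gapdh at 11.888 and 14.996 RPKM. For Eno1 and Gapdh a loss of reads to copies cannot be told apart from low expression, because the handling of such reads is not given in the sources used here; for the other 5 it would need reads concentrated on the shared part, which stays open because coverage along a gene is not in the table. Depth is argued against as well, because 10 RPKM in a gene of 2000 bases stands for at least 84.1 reads in each library. Losses of particular transcripts at capture or amplification, and low expression itself, stay open.

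For 424 genes at 100 RPKM or more in 1 cell and below 1 RPKM elsewhere, a choice that bounds the rates, a median of 58.0 reads per 1000000 of the source's reads were counted in another library, and the highest rates joined cells 15 and 18 in both directions, at 771 and 889 per 1000000. In 3 pairs each cell was the top recipient of the other, against a mean of 0.518 and up to 4 with random recipients; 1 of the 3 joined cells 10 and 11, which both hold 10 mesangial markers and the most genes, so low expression of the same genes could raise their rates. Of the 190 pairs, 69 had rates within 2-fold in both directions. That count includes any pair without reads in either direction, and no expected number was computed for it. Over the 190 pairs, square roots of the rates in both directions were correlated at 0.396 after row and column means were removed, a correlation across pairs, which are not independent. When each source's reads were spread in fixed proportions, the highest of 10000 draws gave 0.296. The draws took each read as independent, which amplified reads are not, so their spread may be too narrow. They cannot decide whether free RNA spread alike over all wells was the only source. Without cells 5, 6, 8, 10, 11 and 14, the 6 with at least 4 markers of 1 other type, the correlation was 0.493 and the highest draw 0.423. Without cells 15 and 18 the correlation was 0.304, below the highest draw of 0.330, and 2 of 10000 draws reached it. Misassignment between particular libraries may add to the reads below 1 RPKM. Free RNA spread alike over all wells, carry-over between particular wells and low expression of the same genes in similar cells stay open.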
